A study of Homo sapiens with 5 samples.

How the data were processed

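Summit lists of H3K27ac, H3K4me1 and H3K4me3 ChIP-seq and of ATAC-seq in untreated HepG2 cells were used, 1 library per assay. Cells were grown in standard serum-containing medium, and the antibodies against the histone marks came from a commercial supplier, per the labels. The input DNA library of the series was not used here, and whether it served as a control for peak calling is not given in the sources used here. The submitters' processing notes name Bowtie, Picard, deepTools and MACS2 and the genome build hg38, without roles or versions. Handling of duplicates, read shifting for ATAC-seq and peak-calling options are not given in the sources used here.

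Each file lists 1 position of 1 bp per peak with a score, the −log10 of the peak caller's q-value or p-value, as deposited by the authors. Which of both it is was not stated. The lowest score in every list was just above 1.3, the −log10 of 0.05. Such a score grows with read depth and with the local number of reads, so it was used to describe, rank or filter summits within a list, and to compare chromosomes within a list, and peak widths and read counts were not analysed here. A list of more summits can reflect deeper sequencing as well as a more widespread mark, and lists were therefore also compared at 10000 summits each. Peak names carried a single library and no pooling was recorded. Summits on chromosomes 1 to 22, X and Y were used, and 105 H3K27ac, 113 H3K4me1, 125 H3K4me3 and 264 ATAC summits on other scaffolds were left out of the comparisons.

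Gene positions came from a RefSeq gene table of the same build, with 20037 protein-coding genes on these chromosomes. The design, fixed before the data were examined, called for transcript starts. The table gives the extent of each gene without strand or individual starts, so either end of a gene was used in their place. A summit counted as at a gene end within 1 kb of an end of a protein-coding gene and as distal more than 2.5 kb from both ends of every annotated gene of any type, which leaves promoters inside genes among the distal sites. Gene extents include predicted transcripts, so an unmarked end does not show that a gene lacks a marked promoter, and a promoter's highest summit can lie beyond 1 kb, as inside ALB. Signed distances are positive towards the inside of the gene. Summits of 2 lists were shared when within 1 kb. As background, all summits of a list were moved by 1 random offset of at least 1 Mb per chromosome, 100 times.

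For 22 gene lists fixed before the data were examined, the number of protein-coding members with a summit at an end was compared with 10000 random lists of the same size, matched on the number of RefSeq transcripts per gene in place of the number of starts. The median number of distal summits within 50 kb of a member's ends was compared with 10000 random lists matched on the number of protein-coding gene ends within 50 kb, in 10 bins. Percentiles describe these libraries and are not p-values. Neighbouring members of a list, such as APOA1 and APOC3 or C1R and C1S, can share summits, which the random lists do not mirror, and KRT19, SOX9 and DES each belong to a pair of lists. H19 of the fetal list is not protein-coding and was left out. The score of a gene is that of its highest summit within 1 kb of an end. Distal H3K27ac summits up to 12 kb apart were stitched into clusters. Motif counts and matching on CpG content need a genome sequence, which was not used here.

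The genes named were chosen by a rule fixed before the data were examined. It takes the 2 members of each list with the most and the 2 with the fewest distal H3K27ac summits. It also takes the genes at the 20 H3K27ac clusters with the most summits and at the 5 highest summits of each list. The rule adds 30 genes set in advance, among them ALB, HNF4A, MYC, GAPDH and PTPRC. Some genes that the rule takes are not reported here. APOC3 and AFM were named outside it, after their values were seen, as neighbours of APOA1 and AFP, and KRT19, SOX9, DES and H19 for their place in the lists.

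Shares are given with exact Clopper-Pearson 95% intervals. The alternatives tried were windows of 500 bp and 2 kb, scores of at least 10, the 10000 highest summits of each list, summits within 500 bp counted once, ends of all annotated genes, windows of 25 kb and 100 kb for distal summits, 5 kb stitching and ranking of clusters by summed score. A distal limit of 10 kb and matching of random lists on gene length were added after the data were seen. The code was tested on simulated summit lists: shares at gene ends were recovered within 0.0109 percentage points and shares of distal overlap within 0.635, 5% of 200 random lists of 24 genes fell in either 2.5% tail, and a list with 20 of 24 marked members came at percentile 99.92. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.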

Results

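HepG2 is a human liver cancer cell line, and the labels describe the cells as untreated hepatocellular carcinoma cells. The series asked where 3 histone marks and open chromatin lie along the genome of these cells. H3K27ac is found at active promoters and enhancers, H3K4me1 is typical of enhancers, H3K4me3 is typical of promoters, and ATAC-seq marks DNA that a transposase can reach. Of the 5 libraries of the series, 4 were used here, 1 per assay, and the input DNA library was not analysed here. The lists held 67216 summits for H3K27ac, 79676 for H3K4me1, 49288 for H3K4me3 and 44495 for ATAC, each summit being the highest point of 1 peak. The median summit score, on the authors' −log10 scale, was 8.07 for H3K27ac, 3.87 for H3K4me1, 9.54 for H3K4me3 and 7.24 for ATAC. A score of 10 was reached by 43.5% of the H3K27ac summits, 4.18% for H3K4me1, 48.2% for H3K4me3 and 36.9% for ATAC, and scores of different libraries are not on a common scale. There were no replicates, so no difference between libraries was tested, and the read depth of each library is unknown. The 95% intervals are exact Clopper-Pearson intervals that cover counting error only, since neighbouring summits are not independent.

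The first comparison asked where each feature lies relative to protein-coding genes. H3K4me3 was the most concentrated at gene ends, with 33.0% of its 49163 summits on the main chromosomes within 1 kb of an end (95% interval 32.6 to 33.4). ATAC followed with 24.9% of 44231 summits (24.5 to 25.4) and H3K27ac with 22.9% of 67111 (22.6 to 23.2), while H3K4me1 had 4.62% of 79563 (4.47 to 4.76). Over the mean of 100 shifts of the summits along their chromosomes, these shares were 11.5-fold for H3K4me3, 9.55-fold for ATAC, 8.39-fold for H3K27ac and 1.77-fold for H3K4me1. Distal regions, more than 2.5 kb from either end of every annotated gene, held 74.6% of H3K4me1 summits, 59.1% of H3K27ac, 58.5% of ATAC and 41.7% of H3K4me3, against 85.3% to 85.9% after shifting. Summits at gene ends scored higher than distal ones for H3K4me3 (median 51.2 against 6.32), H3K27ac (20.5 against 6.11) and ATAC (12.9 against 5.998), and not for H3K4me1 (3.77 against 4.03). Because the gene table gives no strand, a gene end here is either boundary of the gene, so promoters and 3′ ends are counted together. ATAC and H3K27ac were level within counting error with a 2 kb window (29.0% and 28.6%) and for the 10000 highest summits of each list (46.6% and 46.4%).

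**Figure D1:**
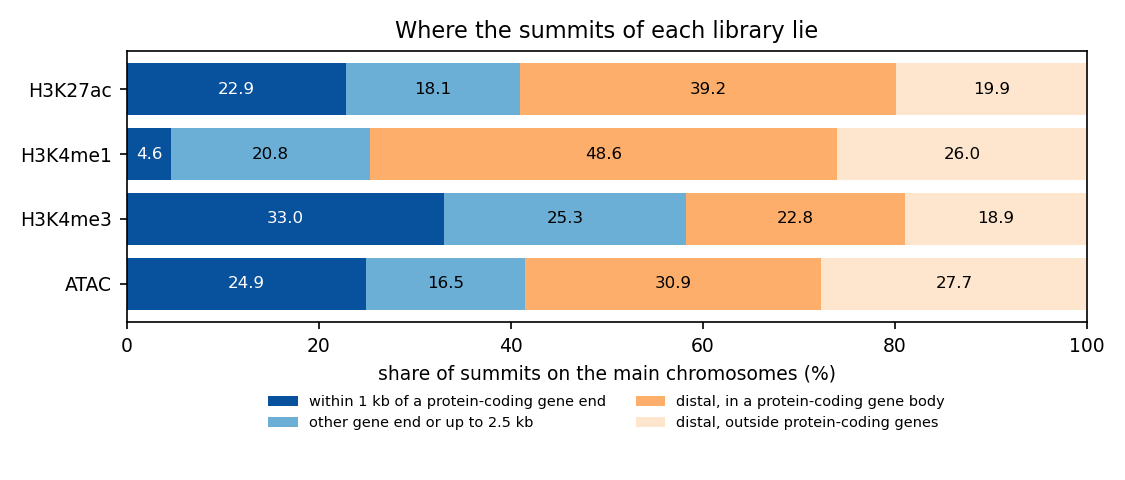
Share of the summits of each library (%) in 4 kinds of place, from within 1 kb of a protein-coding gene end (dark blue) to distal sites outside protein-coding genes (light orange). The dark blue part is 33.0% for H3K4me3 and 4.62% for H3K4me1.

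Around gene ends the open site and the marked nucleosomes took different positions. ATAC summits sat at the boundary itself, with a median 45 bp outside the gene and 45.3% within 100 bp. H3K27ac and H3K4me3 summits lay inside the gene, at medians of 143 bp and 159 bp, and both were most frequent 150 to 200 bp inside. Of the gene-end summits, 63.4% of H3K27ac (62.6 to 64.1) and 66.2% of H3K4me3 (65.4 to 66.9) were on the gene's side of the boundary, against 33.5% of ATAC (32.6 to 34.4). Only 5.38% of H3K27ac and 5.15% of H3K4me3 summits at gene ends were within 100 bp. H3K4me1 showed no peak at the boundary, and within 2 kb its most frequent position was 1700 to 1750 bp inside the gene.

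**Figure D2:**
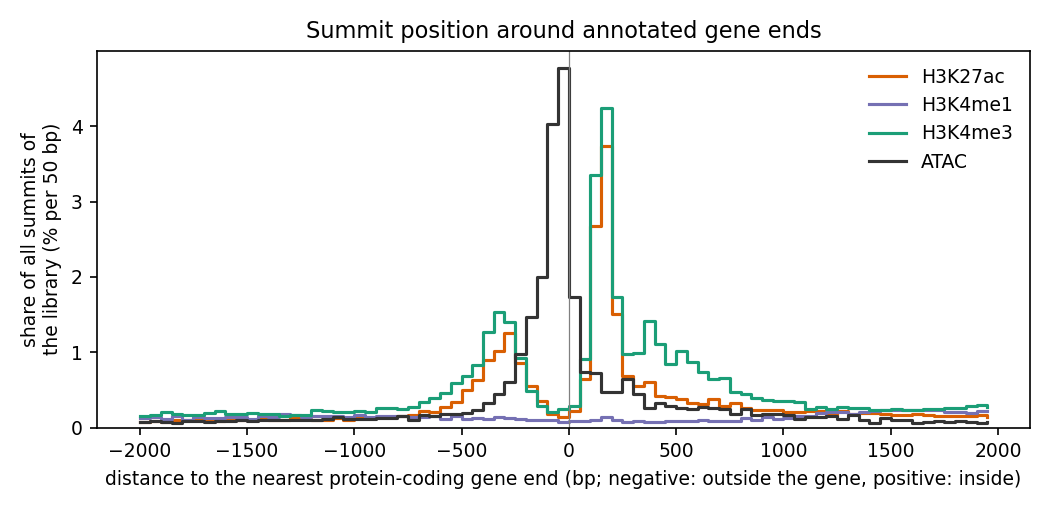
Position of the summits of each library within 2 kb of the nearest protein-coding gene end, in 50 bp bins, as a share (%) of all summits of that library; negative distances lie outside the gene. ATAC peaks from −50 to 0 bp, H3K27ac and H3K4me3 peak from 150 to 200 bp inside with a smaller peak outside, and H3K4me1 has no peak at the boundary.

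At open sites, the marks within 1 kb differed between sites at gene ends and distal sites. At the 11033 ATAC summits at gene ends, 88.5% had an H3K4me3 summit within 1 kb (87.9 to 89.1), 79.9% had H3K27ac (79.1 to 80.6) and 14.5% had H3K4me1 (13.8 to 15.1). There, H3K4me1 was most frequent 950 to 1000 bp from the ATAC summit, at the edge of the window. Its median distance was 577 bp, against 319 bp at distal sites, so its share at gene ends was limited by the window. At the 25886 distal ATAC summits, H3K4me1 came first with 48.4% (47.8 to 49.0), then H3K27ac with 41.0% (40.4 to 41.6) and H3K4me3 with 29.3% (28.7 to 29.8). These distal shares were 10.9-fold, 12.1-fold and 10.5-fold over shifted summits. The most frequent distal class had no histone summit (9601 sites, 37.1%), followed by H3K4me1 with H3K27ac (4862 sites, 18.8%), all 3 marks (3611 sites, 13.9%) and H3K4me1 alone (3277 sites, 12.7%). From the lowest to the highest of 5 equal groups of distal sites by ATAC score, the share with H3K27ac went from 21.9% to 71.2%, with H3K4me1 from 34.0% to 68.6%, with H3K4me3 from 17.7% to 47.4%, and with none from 56.5% to 11.1%. Where distal H3K27ac was the starting point, 72.8% of its 39646 summits had H3K4me1 within 1 kb and 40.1% had ATAC. The order of the marks at distal sites depended on the setting: H3K27ac was level with H3K4me1 within counting error with a 500 bp window (37.5% and 36.9%), and came before it with the 10000 highest summits of each list (33.3% against 27.5%) and with scores of at least 10 (53.3% against 9.26%). That score limit kept 4.18% of H3K4me1 and 43.5% of H3K27ac summits, so the order under it says little about the marks.

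**Figure D3:**
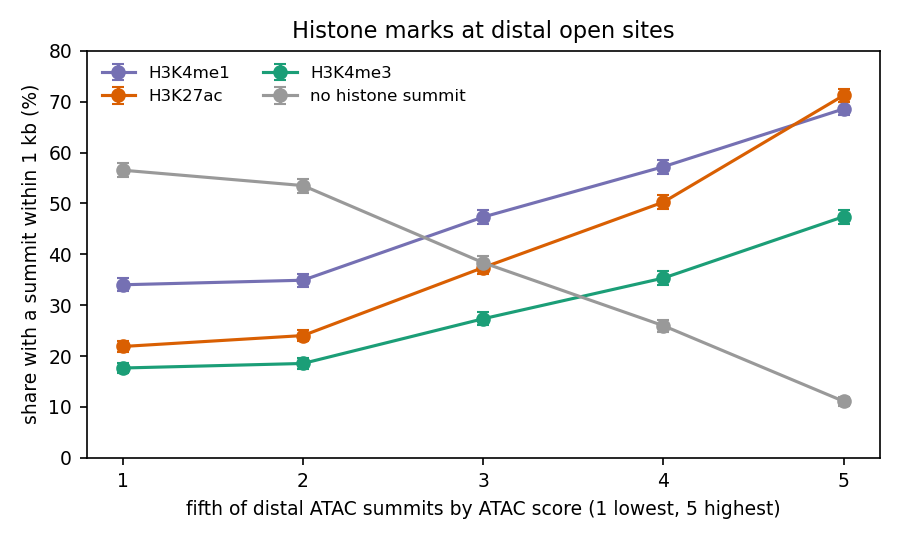
Share (%) of distal ATAC summits with a summit of each histone mark, or of none, within 1 kb, in 5 equal groups by ATAC score; bars are exact 95% intervals for counting error. Sites with no histone summit go from 56.5% in the lowest group to 11.1% in the highest.

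Of the 20037 protein-coding genes in the table, 12378 had an H3K4me3 summit at an end (61.8%), 11477 had ATAC (57.3%), 10521 had H3K27ac (52.5%) and 3021 had H3K4me1 (15.1%). Near gene ends, H3K4me1 was most frequent 1700 to 1750 bp inside the gene, beyond this 1 kb window. The commonest combination within 1 kb was H3K27ac, H3K4me3 and ATAC without H3K4me1, at 7469 genes (37.3%). GAPDH, an enzyme of glycolysis, and ACTB, which encodes beta-actin, were in this class, with H3K27ac scores of 65.5 and 74.1 and H3K4me3 scores of 115 and 85.3. A further 6261 genes (31.2%) had no summit of any list at an end, among them PTPRC, CDH5, COL1A1, NEUROD1, MYOD1, POU5F1 and INS, which mark blood, endothelial, fibroblast, neuronal, muscle, pluripotent and pancreatic beta cells. COL1A1 had its nearest ATAC summit at 1087 bp. H3K4me3 without H3K27ac was found at 2430 genes, with a median H3K4me3 score of 14.1 and ATAC at 56.6%, against 76.3 and 92.6% at the 9948 genes with both. TERT, which encodes the catalytic subunit of telomerase, was one of these, with H3K4me3 at 13.1, ATAC at 10.97 and the nearest H3K27ac summit 49799 bp away. MYC had H3K27ac (31.8) and ATAC (15.0) and its nearest H3K4me3 summit at 1110 bp.

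Genes of plasma proteins, apolipoproteins, hepatocyte transcription factors and complement carried H3K27ac and H3K4me1 at their ends more often than random genes matched on the number of annotated transcripts. Of 24 genes for plasma proteins secreted by the liver, 20 had H3K27ac and 15 had H3K4me1, against random medians of 50% and 12.5%, which placed the list at percentiles 99.96 and 100 of 10000 random lists. H3K4me3 was found at 19 of them (percentile 98.6) and ATAC at 17 (percentile 96.2). Of 19 genes of apolipoproteins and lipoprotein handling, 17 had H3K27ac, 13 H3K4me1, 16 H3K4me3 and 12 ATAC (percentiles 100, 100, 99.5 and 83.5). APOB, the structural protein of low-density lipoprotein, had scores of 135 for H3K27ac, 138 for H3K4me3 and 16.5 for ATAC, and APOA1, the main protein of high-density lipoprotein, had 89.5, 92.7 and 18.8. Of 25 hepatocyte transcription factors, 21 had H3K27ac, 12 H3K4me1, 21 H3K4me3 and 18 ATAC (percentiles 99.9, 100, 98.4 and 89.4). HNF4A, FOXA1 and CEBPA had all 4 features, with H3K27ac scores of 55.3, 82.5 and 52.5. FOXA2 had H3K27ac (2.33) and H3K4me1 (5.39) at its ends. Its nearest ATAC and H3K4me3 summits lay just outside the 1 kb window, at 1045 bp and 1398 bp. Of 25 complement and coagulation genes, 19 had H3K27ac, 15 H3K4me1, 19 H3K4me3 and 18 ATAC (percentiles 99.0, 100, 93.0 and 93.2). Places in the upper 2.5% that were lost under some settings were those of plasma proteins for H3K27ac (lowest percentile 95.8) and H3K4me3 (11.7), apolipoproteins for H3K4me1 (93.7) and H3K4me3 (93.25), transcription factors for H3K27ac (93.7), H3K4me1 (43.1) and H3K4me3 (64.8), and complement genes for H3K27ac (95.9). These values came with the 10000 highest summits for plasma proteins, with a 500 bp window for the H3K4me3 places of the apolipoprotein and transcription factor lists, and with scores of at least 10 for the rest, while with a 500 bp window plasma proteins for ATAC (98.975) and complement genes for H3K4me3 (98.5) entered the upper 2.5%. Only 4.18% of H3K4me1 summits had scores of at least 10. Few genes kept H3K4me1 at an end with that limit, so its H3K4me1 percentiles rest on few or no members and say little.

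The drug and steroid metabolism list was in the lowest 2.5% of random lists for H3K4me3 and ATAC. Of its 25 genes, 9 had H3K27ac, 7 H3K4me1, 9 H3K4me3 and 6 ATAC at an end (percentiles 11.6, 95.5, 1.92 and 0.23), and 13 had no summit of any list. CYP3A4, a main drug-metabolising cytochrome P450, had none at its ends but had 21 distal H3K27ac summits within 50 kb, and POR, the reductase that supplies cytochromes P450 with electrons, had 22 together with H3K27ac (47.7) and H3K4me3 (98.5) at an end. ADH1A and ADH1B, alcohol dehydrogenases, had 0 distal H3K27ac summits. Of 21 bile acid genes, 14 had H3K27ac, 10 H3K4me1, 11 H3K4me3 and 13 ATAC (percentiles 92.8, 99.99, 23.2 and 70.9). CYP27A1 and AKR1D1, enzymes of bile acid synthesis, had 20 and 22 distal H3K27ac summits, while CYP7A1, the rate-limiting enzyme, had ATAC (8.52) but no histone summit at its ends, and the bile salt pump gene ABCB11 had no summit there and 0 distal H3K27ac. Of 18 genes of the urea cycle and amino acid breakdown, 11 had H3K27ac, 5 H3K4me1, 14 H3K4me3 and 13 ATAC (percentiles 80.5, 91.9, 94.0 and 92.8). CPS1, the first enzyme of the urea cycle, had ATAC at 26.7 and H3K27ac at 5.51, and its nearest H3K4me3 summit at 1039 bp. Of 19 fetal liver and tumour markers, 8 had H3K27ac, 6 H3K4me1, 11 H3K4me3 and 11 ATAC (percentiles 16.3, 96.1, 32.4 and 48.4). AFP and GPC3, markers of liver tumours, had H3K27ac at 45.1 and 70.4 and H3K4me3 at 84.1 and 65.7, and IGF2 had no summit at its ends. The nearest ATAC, H3K4me3 and H3K27ac summits of IGF2 lay at 2231, 5376 and 7994 bp. The drug metabolism list entered the lowest 2.5% for H3K27ac with a 500 bp window (percentile 0.84) and with matching on gene length (1.515), and the upper 2.5% for H3K4me1 with a 500 bp window (99.39). The fetal list entered the lowest 2.5% for H3K4me3 (0.92) and ATAC (0.08) with the 10000 highest summits, and the bile acid list the upper 2.5% for H3K27ac with a 2 kb window (98.35).

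Lists of general cell functions were mostly marked at gene ends. All 22 cell cycle genes and all 24 ribosomal protein genes had H3K27ac, H3K4me3 and ATAC at an end (percentile 100 each), and 5 and 3 of them had H3K4me1 (percentiles 83.6 and 39.6). PCNA, the DNA polymerase clamp, had an ATAC score of 68.5, and RPLP0 had H3K27ac at 67.1 and H3K4me3 at 96.5. Of 24 histone and DNA modifying enzymes, 23 had H3K27ac, 4 H3K4me1, 20 H3K4me3 and 21 ATAC (percentiles 100, 58.6, 96.4 and 99.7). Of 21 genes of cholesterol and fatty acid synthesis, 18 had H3K27ac, 2 H3K4me1, 19 H3K4me3 and 18 ATAC (percentiles 99.8, 24.4, 99.5 and 99.3), among them SCD, a fatty acid desaturase, at 68.2 for H3K27ac and 88.7 for H3K4me3. Of 18 beta-catenin target genes, 14 had H3K27ac, 5 H3K4me1, 16 H3K4me3 and 15 ATAC (percentiles 98.6, 92.0, 99.5 and 98.9). Of 21 genes of glycolysis and gluconeogenesis, 15, 6, 17 and 13 had H3K27ac, H3K4me1, H3K4me3 and ATAC (percentiles 94.5, 94.2, 95.5 and 59.8). Of 19 NRF2 target and iron genes, these counts were 15, 9, 15 and 15 (percentiles 99.6, 99.9, 97.2 and 98.8). The upper 2.5% was left with a 500 bp window by the beta-catenin list for H3K27ac (41.4) and H3K4me3 (67.8), the cholesterol list for H3K4me3 (95.535) and ATAC (94.3) and the NRF2 and modifying enzyme lists for ATAC (96.2 and 94.6), and with the 10000 highest summits by the NRF2 list for H3K27ac (68.0), H3K4me1 (97.1) and ATAC (87.1), the modifying enzyme and ribosomal lists for ATAC (17.1 and 92.7) and the beta-catenin and cholesterol lists for H3K4me3 (90.7 and 95.48). It was entered under at least 1 setting by the glycolysis list for H3K27ac and H3K4me1, and the modifying enzyme and NRF2 lists for H3K4me3. For H3K4me1 with a 2 kb window it held the beta-catenin (99.97), cholesterol (99.97), cell cycle (99.695) and glycolysis (98.325) lists. With that window a high H3K4me1 percentile therefore did not set the liver lists apart from these lists. The ribosomal (85.5) and modifying enzyme (76.4) lists stayed outside it.

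Markers of other cell types had few marks. H3K27ac was found at an end of 3 of 22 blood cell markers, 2 of 20 endothelial, stellate and fibroblast markers, 5 of 20 cholangiocyte and other epithelial markers, 1 of 20 neuronal markers, 0 of 18 muscle markers and 2 of 20 germ line and pluripotency markers, all in the lowest 2.5% of random lists (percentiles 0.02, 0, 1.45, 0, 0 and 0). H3K4me3 was found at 5, 1, 7, 5, 1 and 3 members (percentiles 0.005, 0, 1.82, 0.03, 0 and 0) and ATAC at 5, 4, 8, 7, 2 and 3 (percentiles 0.07, 0.04, 11.2, 2.1, 0 and 0.01). H3K4me1 was found at 5, 1, 5, 2, 1 and 4 members, within the range of random lists (percentiles 83.5, 10.3, 88.9, 28.5, 13.6 and 73.6). Among the exceptions, 4 epithelial markers had all 4 features. CDX2, an intestinal transcription factor, had H3K27ac at 32.8, H3K4me3 at 33.1 and ATAC at 20.3 without H3K4me1. PECAM1, an endothelial adhesion molecule, had H3K27ac at 5.33 and ATAC at 14.5. SPI1, a blood cell transcription factor, had H3K4me3 at 10.98 and ATAC at 7.29 without H3K27ac, and CD3E of T cells had only an H3K4me1 summit of score 1.63. Of 24 HOX genes, 2 had H3K27ac, 2 H3K4me1, 9 H3K4me3 and 5 ATAC (percentiles 0.01, 20.3, 7.57 and 0.37), and 7 had H3K4me3 without H3K27ac, HOXA13 among them at an H3K4me3 score of 15.5. HOXD1 had H3K27ac at 125 and H3K4me3 at 75.6. The lowest 2.5% was left by the epithelial list for H3K27ac with scores of at least 10 (5.32) and with the 10000 highest summits (8.875), and with a 2 kb window by the neuronal list for H3K4me3 (6.12) and ATAC (12.4) and by the HOX list for ATAC (24.6). It was entered with a 2 kb window by the endothelial and muscle lists for H3K4me1 (0.995 and 0.43), and with scores of at least 10 by the HOX list for H3K4me3 (0.395) and the epithelial list for ATAC (0.49).

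**Figure D4:**
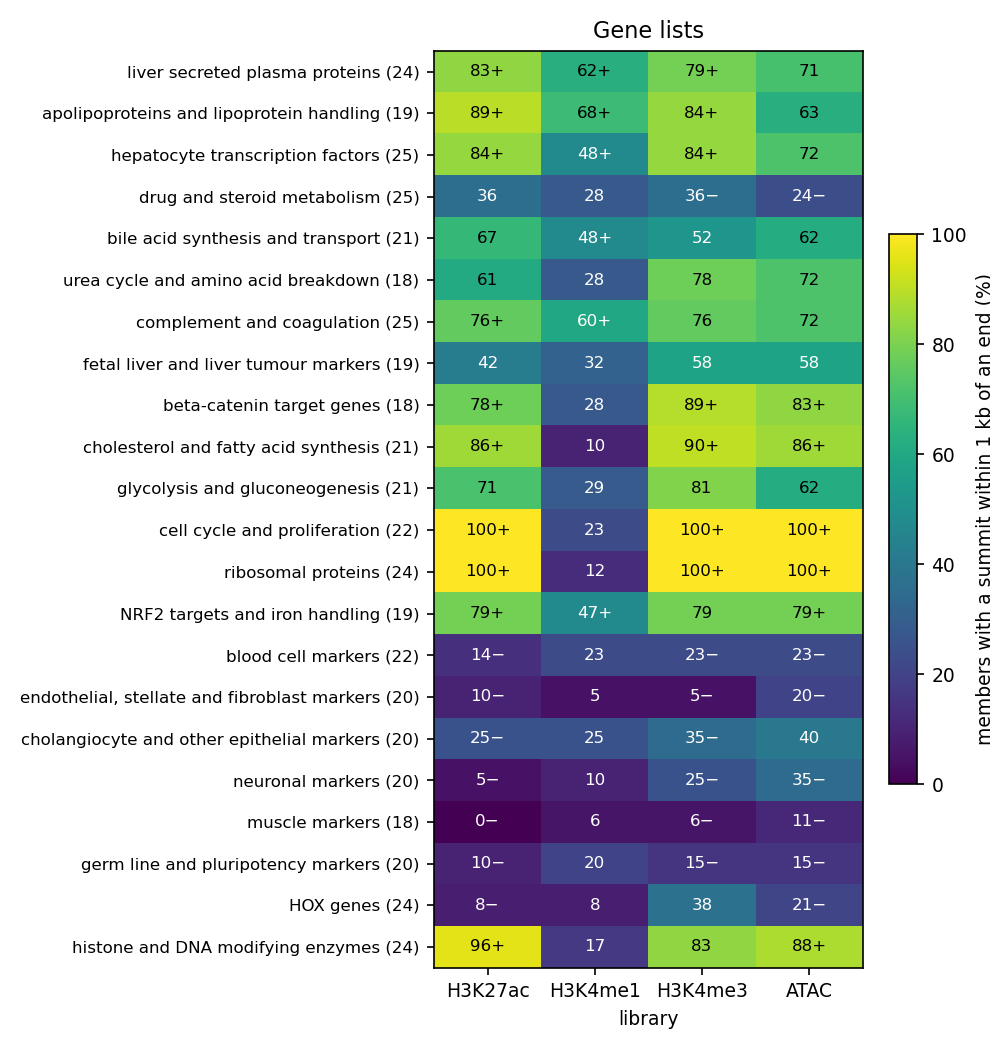
Share (%) of the members of each gene list with a summit of each library within 1 kb of an end; the number of members is in brackets. A plus or minus marks shares in the upper or lowest 2.5% of random lists matched on the number of transcripts, such as 83% for H3K27ac in plasma protein genes and 0% in muscle markers.

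Distal H3K27ac was most frequent around genes of liver functions and beta-catenin targets. The median gene of the table had 1 distal H3K27ac summit within 50 kb of its ends. The medians were 8 for apolipoprotein, 7 for beta-catenin target, 6 for bile acid, 5.5 for plasma protein, 5 for hepatocyte transcription factor and 4.5 for urea cycle genes (percentiles 99.995, 100, 99.9, 99.97, 99.9 and 99.1 of random lists matched on nearby gene ends). Drug metabolism, cholesterol, glycolysis, NRF2 and modifying enzyme genes had medians of 4 (percentiles 99.5, 99.0, 98.6, 98.8 and 99.2), complement genes 3 (94.9), and fetal, cell cycle and ribosomal genes 2 (84.2, 76.9 and 76.1). Blood, endothelial, epithelial, muscle and HOX lists had medians of 0 (percentiles 6.04, 20.4, 12.1, 9.72 and 2.74), and neuronal and germ line lists 0.5 (40.3 and 34.7), and none of these was in the lowest 2.5% with this window. Neighbouring members of a list, such as APOA1 and APOC3, can share distal summits within 50 kb. The random lists do not mirror this, so the percentiles can overstate how unusual a list is. The most distal H3K27ac among list members was at ZNRF3, a negative regulator of WNT signalling, with 58 summits, followed by SCARB1, a receptor for high-density lipoprotein, with 38, and by SERPINA1, which encodes alpha-1 antitrypsin, and the glucose transporter gene SLC2A2 with 34 each. LIPC and NKD1 had 29, PROX1 28, AKR1C3 27, NR0B2 25 and HNF4A 23. HPX, TERT, MYC, GOLM1 and PTPRC had 0. These counts were not adjusted for gene length. The windows around both ends overlap in short genes such as HPX (9939 bp) and not in ZNRF3 (173917 bp), so more sequence was searched around ZNRF3. The modifying enzyme list left the upper 2.5% in each of the 5 alternative settings, the plasma protein list with a 25 kb window (88.1), and the glycolysis and NRF2 lists with scores of at least 10 (88.8 and 90.5). With a 100 kb window the fetal and complement lists entered the upper 2.5% (99.3 and 98.5) and the HOX list the lowest (0.375).

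The region of ALB and AFP, the genes of albumin and alpha-fetoprotein, held 30 H3K27ac, 34 H3K4me1, 11 H3K4me3 and 8 ATAC summits between positions 73354287 and 73506174 of chromosome 4 (hg38). The highest H3K27ac summit of the region (124) lay at 73432539, between the genes and 3682 bp from the nearer end of AFP, beside the highest ATAC summit (21.3, at 73432787). Inside ALB (73404287 to 73421482), H3K4me3 reached 105 at 2269 bp and H3K27ac reached 70.4 at 1013 bp from the lower-coordinate end, so both fell outside the 1 kb window, and the H3K4me3 and H3K27ac summits counted for ALB had scores of 4.49 and 2.48. H3K4me1 covered the flank of ALB with a highest score of 13.5 at 73398365. ALB had 22 and AFP 18 distal H3K27ac summits within 50 kb.

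**Figure D5:**
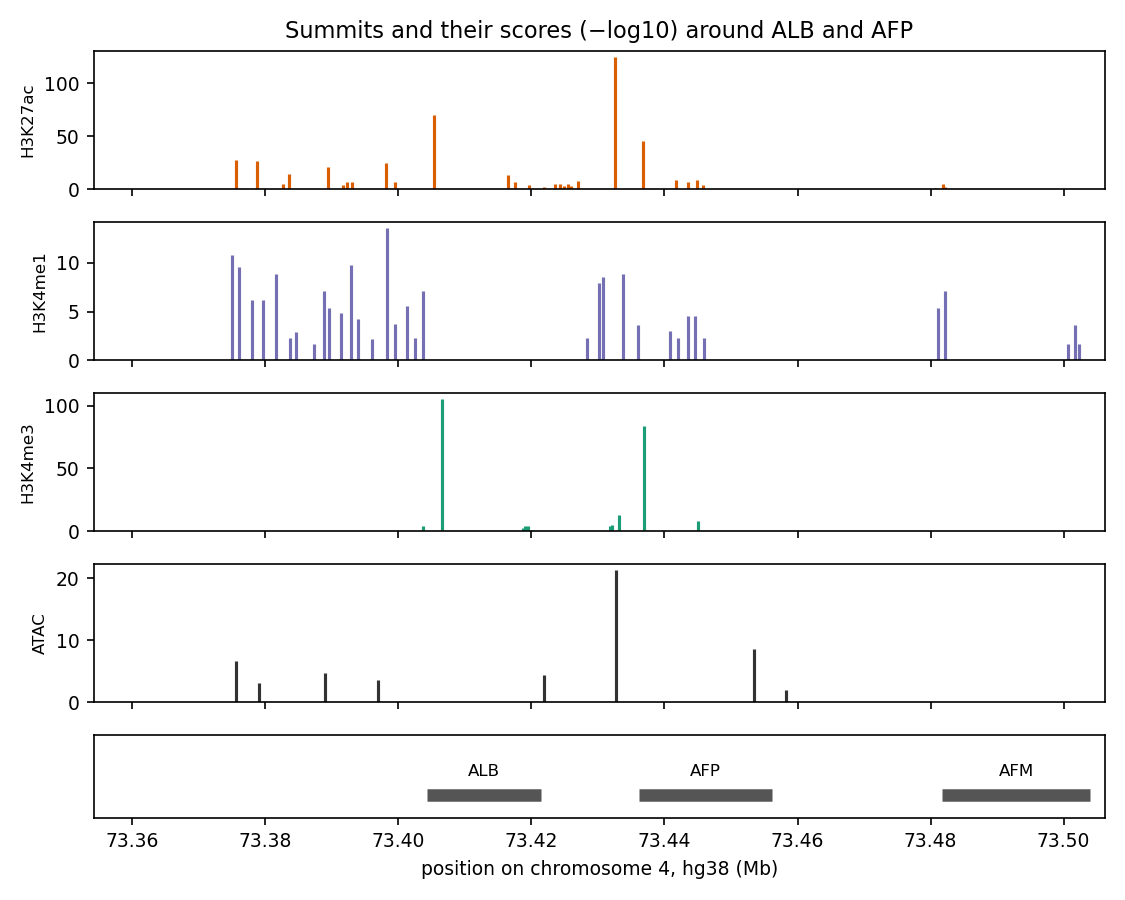
Summits (vertical lines, height is the −log10 score, a separate scale per library) and protein-coding genes (grey bars) around ALB, AFP and AFM on chromosome 4. The highest H3K27ac and ATAC summits, with scores of 124 and 21.3, stand between ALB and AFP.

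Distal H3K27ac summits stitched across gaps of up to 12 kb formed 11730 clusters, of which 4241 held a single summit and 721 held at least 10, with 27.9% of all distal H3K27ac summits. Clusters were ranked by their number of summits, not per kb, and the first 20 spanned 49.2 to 163.7 kb. The cluster with the most summits held 62, on chromosome 19 (56875615 to 56982141). It had no gene end inside, and its nearest protein-coding gene end, of LOC124904779, lay 58307 bp from its midpoint. It was followed by 60 summits inside SPTBN1 on chromosome 2 (54523507 to 54634233), 58 at FNDC3B on chromosome 3 (172029673 to 172154765), 57 at COBLL1 and SLC38A11 and 47 at MAP4K4, both on chromosome 2, 46 in a further cluster of that chromosome with no gene end inside (42928560 to 43024037), and 45 inside ZNRF3 on chromosome 22 (28887711 to 28956827). Others of the first 20 were inside or at ARHGAP18, LGSN, ZMIZ1, VAC14 and MTSS2, SHB, WDFY2, TFPI, SLC2A2, SYNJ2 and NOX3. TFPI encodes an inhibitor of coagulation and SLC2A2 the main glucose transporter of hepatocytes. Chromosomes 2 and 6 held 5 and 4 of the 20. Of these 20, 14 were among the top 20 with 5 kb stitching and 11 with ranking by summed score. The 20 include a cluster of 43 summits on chromosome X (115843535 to 115892908), which was not told apart from a mapping artefact.

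The highest single summits lay partly at gene ends and partly far from them. For H3K27ac the first was a site on chromosome 14 at 34556504 (score 208), 4589 bp from SNX6 and 115 bp from an annotated gene end of any type. Sites nearest DCAF11 (169), PLS3 (169), FCGBP (168) and MLLT6 (166) followed. For H3K4me3, the first was on chromosome 2 at 113584405 (233.9), 16415 bp from LOC124907874 and 359 bp from an annotated gene end of any type. Others were at PSMB5 (180), a proteasome subunit, and PABPN1 (177), a poly(A)-binding protein. The highest H3K4me1 summits, of 24.4 to 26.1, were distal, nearest DHRS2, BCL2L1, PTPN1, JPH4 and SH3BP4. The highest ATAC summit (181, chromosome 3 at 93470608) had no histone summit within 1 kb. It lay 402443 bp from its nearest protein-coding gene end, that of PROS1. Regions prone to mapping artefacts were not filtered out here, so this summit was not told apart from such an artefact. The ATAC summits nearest CCDC200 (116), NID1 (107) and MXD1 (94.5) had H3K27ac and H3K4me3. The one nearest CCDC200 lay 20 bp from an annotated gene end of any type. Scores differed by chromosome: over genes with H3K27ac, H3K4me3 and ATAC at an end, the median H3K27ac score was 48.5 on chromosome 20, which carries HNF4A and FOXA2, 43.6 on chromosome 2, which carries APOB, and 17.3 on chromosome X, which carries GPC3. A ranking of scores over the genome carries this difference between chromosomes with it.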

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

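No test was run on the counts in this part. Summits on unplaced or unlocalised scaffolds entered no comparison, and each list held more of them than the 3 that a count of 0 allows. There were 105 for H3K27ac, 113 for H3K4me1, 125 for H3K4me3 and 264 for ATAC, which is 0.156%, 0.142%, 0.254% and 0.593% of the lists.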

How the results depend on the processing

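The distal limit of 10 kb and the matching of random lists on gene length were chosen after the results were seen; the other settings were planned. The order H3K4me3, ATAC, H3K27ac, H3K4me1 at gene ends held in 6 of the 6 alternative settings that can change it, although ATAC and H3K27ac were level within counting error at 2 kb and with the 10000 highest summits, and the order H3K4me1, H3K27ac, H3K4me3 at distal ATAC summits in 3 of 6, with the changes at 500 bp, scores of at least 10 and the 10000 highest summits. Of 74 alternative values of the main shares and counts, 52 moved beyond their counting interval or by over 1.5 times, and 22 did not. Of the 88 shares of list members at gene ends, 70 moved beyond their counting interval with the 10000 highest summits, 42 with scores of at least 10 and 14 at 500 bp, all downwards, and 15 at 2 kb, all upwards. Of the 22 list medians of distal H3K27ac, 7 rose beyond their interval at 100 kb and 4 fell with scores of at least 10. No list changed from the upper to the lowest 2.5% of random lists or back under any setting. The cause of a change was not tested unless the setting itself gives it: a wider window or more gene ends can only raise a share with a summit nearby and lower the share with none, and higher score limits leave fewer summits. Unknown read depth limits all comparisons of list length. No paired analysis was possible because each assay has 1 library with no replicate numbers, and no library could be left out. Starts of the longest transcript, matching on CpG content and all motif settings were not run, since the table gives no starts and no genome sequence was used.

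The shares of H3K27ac, H3K4me1, H3K4me3 and ATAC summits at gene ends were 17.9%, 2.09%, 23.8% and 21.2% within 500 bp, 28.6%, 11.6%, 42.1% and 29.0% within 2 kb, 38.5%, 3.64%, 55.4% and 40.9% with scores of at least 10, 46.4%, 3.66%, 77.8% and 46.6% for the 10000 highest summits, and 29.2%, 9.92%, 41.7% and 32.5% with ends of all annotated genes. With summits within 500 bp counted once, that of H3K27ac was 21.998%. With the 10000 highest summits, 4816 genes had H3K27ac, 369 H3K4me1, 8073 H3K4me3 and 5493 ATAC at an end. For H3K4me1 the number of genes was 1541 within 500 bp, 6619 within 2 kb and 125 with scores of at least 10.

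Distal ATAC summits with H3K4me1, with H3K27ac, with H3K4me3, with no histone summit and with H3K4me1 and H3K27ac alone made up 36.9%, 37.5%, 25.5%, 40.4% and 15.0% within 500 bp, and 53.2%, 42.9%, 31.2%, 35.5% and 19.5% within 2 kb. They made up 9.26%, 53.3%, 24.2%, 39.0% and 6.84% with scores of at least 10, and 27.5%, 33.3%, 7.20%, 51.3% and 15.4% for the 10000 highest summits. Beyond 10 kb from gene ends, the first 4 were 46.6%, 38.4%, 25.1% and 40.9%. The number of lists in the upper 2.5% for H3K27ac at gene ends was 10, and 8 to 12 under the alternatives, and in the lowest 2.5% it was 7, and 6 to 8. Lists that left a 2.5% tail under at least 1 setting were, for H3K27ac at gene ends, the NRF2, epithelial, plasma protein, beta-catenin, transcription factor and complement lists; for H3K4me1 the NRF2, transcription factor and apolipoprotein lists; for H3K4me3 the apolipoprotein, beta-catenin, cholesterol, plasma protein, transcription factor and neuronal lists; and for ATAC the NRF2, modifying enzyme, ribosomal, HOX, neuronal and cholesterol lists. Lists that entered one were, for H3K27ac at gene ends, the drug, glycolysis and bile acid lists; for H3K4me1 the drug, beta-catenin, cholesterol, glycolysis, cell cycle, endothelial and muscle lists; for H3K4me3 the complement, HOX, modifying enzyme, NRF2 and fetal lists; and for ATAC the plasma protein, epithelial and fetal lists.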

Other observations

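The gene families, the non-coding genes, the test of weak ATAC summits and the test of DNA copy number were chosen after results had been seen; the other tests were set before theirs were. Of 15 gene families picked by symbol, 517 genes of the ZNF-numbered zinc finger group had H3K27ac at 70.0%, H3K4me3 at 77.8% and ATAC at 72.5% (percentile 100 each), but H3K4me1 at 6.58% (percentile 0) and a median of 0 distal H3K27ac summits within 50 kb (percentile 0.01). Of 77 mitochondrial ribosomal protein genes, 96.1% had H3K27ac, 97.4% H3K4me3 and 93.5% ATAC, and of 40 proteasome subunit genes 92.5%, 90.0% and 87.5%. Of 392 olfactory receptor genes, 0.765% had H3K27ac and 1.53% ATAC. Protocadherins had H3K4me3 at 28.8% of 66 genes and H3K27ac at 3.03%. Cytochromes P450 had H3K27ac at 17 of 56 genes (percentile 0.11) and UDP-glucuronosyltransferases, which conjugate drugs and bilirubin, at 3 of 20 (percentile 0.14), while 13 aldo-keto reductase genes had a median of 10 distal H3K27ac summits (percentile 99.99). AKR1C2 and AKR1C3, neighbours on chromosome 10, had 24 and 27 of these, and AKR1B10 had 0. Neighbouring members of a family can share summits, which the random lists do not mirror.

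Of 18303 lncRNA genes, 22.6% had H3K4me3 at an end, and 10.1% of the 12807 far from protein-coding gene ends did. HNF4A-AS1, which lies within HNF4A (44355699 to 44434596 on chromosome 20), had all 4 features at its ends, of which the H3K27ac (55.3) and H3K4me3 (105) scores were those counted for HNF4A. LINC00261, beside FOXA2, had all 4 too, with H3K4me3 at 125. HULC, a transcript known from liver cancer, had H3K27ac at 31.2, and MIR122HG, the host gene of the liver microRNA miR-122, had H3K27ac at 7.10 and ATAC at 5.97. H19 and MEG3, a pair of imprinted genes, had no summit at their ends.

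Chromosome X had 3.52 H3K4me1 summits per Mb, against at least 15.1 on the autosomes, and 59.7 distal H3K4me1 summits per 100 distal H3K27ac summits, against an autosomal range of 108 on chromosome 19 to 171 on chromosome 15. A lack of distal elements is not the whole cause, although X was also below every autosome in H3K27ac (9.52 summits per Mb, against at least 11.9) and ATAC (6.24 against at least 8.46): where an open distal site with H3K27ac was present, 37.7% of 239 on X had H3K4me1 (31.5 to 44.1), against 81.1% of 10335 on autosomes (80.3 to 81.8). Weak H3K4me1 near the peak threshold cannot be told apart from other causes, since the ratio of these shares was 0.571 at the highest of 3 groups by H3K27ac score and 0.329 at the lowest, with overlapping intervals on X (34.8 to 58.6 and 16.3 to 39.1). DNA copy number stays open: autosomes 2, 14, 16, 17 and 20, known from background as gained in HepG2, averaged 8.20% of H3K4me1 summits at scores of at least 10 against 2.43% on the other 17 (exact one-sided permutation p = 7.59e-05, adjusted over 5 measures 0.000285), gene-end median scores of 39.7 against 31.0 for H3K27ac (exact p = 0.000266, adjusted 0.000443), 92.3 against 74.9 for H3K4me3 (exact p = 0.000114, adjusted 0.000285) and 18.2 against 16.5 for ATAC (exact p = 0.138, adjusted 0.172), but not more distal H3K4me1 per 100 distal H3K27ac summits (148.7 against 151.2, exact p = 0.640, adjusted 0.640). This comparison was chosen after results had been seen, and its p-values and their adjustment do not cover that choice. Copy number was not measured here, X, at 0.182%, 17.3, 41.7 and 11.6, was below every autosome in each of these 4 score measures, chromosome 6, outside the named set, had 6.79%, and no biological explanation was tested.

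Of the H3K4me3 summits, 41.7% were distal. Weak summits are not the whole cause, since 25.5% of the 23699 with scores of at least 10 were distal too (24.9 to 26.1). Of these strong distal summits, 39.3% had H3K4me1 within 1 kb, against 13.5% at gene ends, a ratio of 2.90. How far promoters missing from the gene table, those inside genes included, account for distal H3K4me3 cannot be told from this ratio. Summits at gene ends had H3K4me1 too, and both groups were not matched on score. Over all H3K4me3 summits the median score was 51.2 at gene ends and 6.32 at distal sites. Of the 6044 strong distal summits, 66.7% had ATAC, 61.3% had H3K27ac and 50.8% lay in the body of a protein-coding gene. Antibody cross-reaction stays open, and no biological explanation was tested.

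Of distal ATAC summits, 37.1% had no histone summit within 1 kb. In the highest of 5 equal groups by ATAC score 11.1% had none either (10.3 to 11.99), so unmarked sites were not limited to low scores, although the share did fall with the score. This value had been seen before the test was set, so how far weak ATAC summits account for unmarked sites is not decided by it. Histone summits just beyond the window argue for little of it, with 32.7% still unmarked at 5 kb, or 88.3% of the share at 1 kb. Sites of CTCF and other factors that bind without these marks stay open, as a genome sequence was not used, and no biological explanation was tested.

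The distal H3K27ac cluster on chromosome X from 115843535 to 115892908 held 43 H3K27ac, 46 H3K4me3, 16 ATAC and 12 H3K4me1 summits. The median gap was 2981 bp between its ATAC summits (quartiles 2970 and 2995), 2974 bp between its H3K4me1 summits (2636 and 3345), 946.5 bp for H3K27ac and 878 bp for H3K4me3. Many of its ATAC summits were thus almost evenly spaced. Whether the DNA of this region is repeated was not tested, as a genome sequence was not used. Regions prone to mapping artefacts were not filtered out here. The summits of this cluster, and its rank of 8 by number of summits, were therefore not told apart from such an artefact.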
